A study of Mus musculus with 3 samples.

How the data were processed

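Single-cell ATAC-seq, in which a transposase inserts adapters into accessible chromatin of single nuclei, was performed on whole mouse aorta. Mice of 3 groups were sampled. Mice of the db/db genotype carry a mutated leptin receptor gene and develop obesity and diabetes, and db/+ mice are their heterozygous controls. The db/dbDAPA mice were db/db mice given DAPA by oral gavage for 6 weeks, at 1 mg/kg/day for 4 weeks and then at 3 mg/kg/day for 2 weeks, while the db/db mice received saline; 12 mice were dosed in each of these groups. Per the labels' protocols, aortas of 8 mice per group were pooled into 2 replicates of 4 mice, and 10000 nuclei were processed with a droplet kit. Of these, 1 library per group, labelled replicate 1, was analysed here, 3 libraries in all. The labels place the db/+ library in batch 2 and both db/db libraries in batch 1. A number of dosed mice was recorded for both db/db groups and none for db/+, so whether db/+ mice were gavaged is not known here.

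The submitters' processing notes name Cell Ranger ATAC 1.2.0, ArchR 1.0.1 and the mm10 genome build, with no role for each. Peak calling settings and the treatment of doublets were not given in the sources used here, and no doublets were removed from the barcodes here. The deposited files of each library hold the positions of its called peaks and the barcodes kept as cells. Peaks were listed separately for each library, and positions differ between lists. The lists carry no height, score or count per peak and no fragments per barcode, so sequencing depth is unknown, no interval for it is given, and no cells were clustered. Peak positions are given as the files give them. A matrix of counts was not analysed here.

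Peaks on chromosomes 1 to 19 and X were compared. A peak counted as shared when it overlapped a peak of the other library by at least 1 bp. Peaks of all 3 libraries that overlapped were also merged into regions. Each peak or region was assigned to a promoter if it reached within 1 kb of the transcription start site (TSS) of any transcript, and otherwise by its midpoint to exon, intron or intergenic sequence, using GENCODE M21, which has the same build as the files. For 21728 protein-coding genes, the promoter (1 kb on each side of every annotated TSS) was scored as holding a peak or not. The locus of a gene was its body with 5 kb upstream. Covered base pairs (bp) per locus were scaled to equal total covered length per library, and a log2 ratio was taken after adding 500 bp. After scaling, a locus with the same covered bp in both libraries has a slightly negative ratio when the numerator library covers more in total. Loci that overlap share peaks, and covered bp was preferred to the number of peaks because a peak split into adjacent calls raises the number. Analyses were run in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1.

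With 1 library per group there is no replicate check, and neither a p-value nor a standard error is given. A difference describes these libraries and not the groups. Before the data were examined, 16 cell type lists and 14 pathway lists were fixed, with 499 entries, all of which matched a gene. Each list's median log2 ratio was placed among 10000 random lists of the same size matched on mean covered bp in 20 bins, and was called apart when it lay outside the central 95% of them. By chance 1.5 of the 30 lists would lie outside in a comparison. In a check on the observed ratios, lists of 20 genes were drawn at random from all genes, with or without a peak. With no shift added, 3.5% of 1000 such lists were called apart for db/db over db/+. The share was 3.2% for db/dbDAPA over db/db and 3.3% for db/dbDAPA over db/+. The fixed lists were not drawn this way, so these rates need not carry over to them. With a shift of 0.1 (log2) the shares were 98.7%, 100% and 61.8%, all on 21728 genes. The shift was added to every member, and only lists above the range were counted. Real ratios move by whole peaks in some members alone, so a list that is not apart may still hold a shift. When a fixed share of the peaks was removed from 200 loci of the db/db list, 100% of these loci were recovered. Of the other loci, 0.85% were also called. The shortened list was compared with the full db/db list itself, on the same genes. That checks the calculation and does not show how well differences between libraries are found.

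Genes were named by a rule fixed at the same time. Among genes with at least 4 peaks in the locus in at least 1 library of a pair, the 10 highest and 10 lowest log2 ratios were taken. In each list up to 4 members with the largest absolute log2 ratio were taken, together with every member of the contractile and modulated smooth muscle lists. List members whose promoter peak differed between libraries were also taken, as were Lepr and Slc5a2. Some genes that the rule takes are left out of the text because they are withheld for evaluation. Genes outside this rule are said to have been chosen after their values were seen. The alternatives covered the overlap rule (reciprocal overlap of 0.5, or a gap of up to 250 bp), peak width (peaks at least as wide as the median of their library), list length (the widest 112997 peaks of each library), the X chromosome, the promoter (2 kb, 500 bp, or the 5' end of the gene alone), the locus (10 kb around the TSS), the number of peaks with a pseudocount of 1, pseudocounts of 100 and 1000 bp, the mean over members, matching on locus length, scaling to the median gene, and leaving out genes with no peak. Width stood in for strength, for which the lists give no other measure. After the data were seen, further settings left out the most extreme member of each list and the members of several lists. Also added then were 1000 simulations in which each library called any region with its own odds and which were fitted to the regions found in 1 or 2 libraries. Figures were drawn with matplotlib 3.10.9. Peaks on chromosome Y and on unplaced scaffolds were left out of the comparisons.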

Results

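Accessible chromatin of the whole aorta was profiled in 3 libraries, 1 each from db/+, db/db and db/dbDAPA mice. The db/+ library held 6650 barcodes and 113102 peaks, the db/db library 5170 barcodes and 122864 peaks, and the db/dbDAPA library 8014 barcodes and 129286 peaks. The number of peaks did not follow the number of barcodes, since db/db had the fewest barcodes and more peaks than db/+. Median peak width was 879, 877 and 877 bp in the same order, and the peaks covered 96.4, 104 and 110 Mb. Promoters took 23.6% of peaks in db/+, 22.4% in db/db and 21.8% in db/dbDAPA, and introns 41.7%, 43.0% and 43.4%. There were no replicates, so none of the differences below could be set against a spread between animals.

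Smooth muscle genes were marked in all 3 libraries. All 22 genes of the contractile smooth muscle list had a promoter peak in db/+, db/db and db/dbDAPA alike. Myh11, the smooth muscle myosin heavy chain, held 17, 16 and 19 peaks in db/+, db/db and db/dbDAPA, and Acta2, smooth muscle actin, held 7, 6 and 7. Myocd, the coactivator that drives the contractile programme, held 14, 17 and 19. Lepr, the gene mutated in db mice (chromosome 4, 101717404 to 101815352, mm10), held 2 peaks in each library, including a promoter peak. Slc5a2, which encodes the renal glucose transporter targeted by SGLT2 inhibitors such as dapagliflozin, held 0 peaks in every library. Promoter peaks were no measure of cell type by themselves: 10, 11 and 10 of the 12 neuronal genes, a tissue not sampled, also had one in db/+, db/db and db/dbDAPA, as did 2, 4 and 3 of the 12 hepatocyte genes.

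The comparison of db/db with db/+ addresses which chromatin differs in the diabetic aorta. Chrm2, the muscarinic M2 acetylcholine receptor (chromosome 6, 36388084 to 36528414), held 6 peaks in db/db and 1 in db/+, a log2 ratio of covered bp of 2.25, and all 5 db/db peaks absent from db/+ were intronic. Exoc5, a subunit of the exocyst that tethers secretory vesicles (chromosome 14, 49004090 to 49066653), held 7 and 1 peaks with a log2 ratio of 1.92, and Antxr2, a cell surface receptor that binds matrix proteins (chromosome 5, 97882783 to 98031043), held 5 and 1 with 1.82. On the lower side, Caprin2 (chromosome 6, 148842492 to 148896237) held 1 peak in db/db and 5 in db/+, with a log2 ratio of -1.79. Hrc, a calcium-binding protein of the sarcoplasmic reticulum, held 1 and 4 peaks with -1.31, which became -2.49 with lists of equal length, and Cd83, an activation marker of dendritic cells, held 1 and 4 with -1.45.

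Other genes among the highest ratios were Spata6, Yaf2, Rab14, Psmd11, Stradb and Cpeb2, down to 1.38 for Cpeb2. Those with the lowest were Plekhs1, Flvcr2, Gm20547, Poli, Rcor1, Csrnp3 and Grid1, up to -1.15 for Grid1. Of 41 db/db peaks absent from db/+ in the 10 highest loci, 27 were intronic, 11 lay at a promoter and 3 in an exon. The 3 db/+ peaks absent from db/db in Gm20547 also lay in another gene. Genome-wide, 19947 of 122737 db/db peaks (16.3%) had no overlapping peak in db/+, and 10258 of 112997 db/+ peaks (9.08%) had none in db/db. With lists of equal length, where only the db/db list of this pair was shortened, the second count became 16676.

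Endothelial genes had the highest standing among the 30 gene lists in db/db over db/+. Of 18 members, 11 held more peaks in db/db, 6 the same number and 1 fewer. Their median log2 ratio was 0.11, at percentile 99.3 of random lists, against -0.06 for all genes. The largest ratios were 0.67 for Egfl7, 0.59 for Robo4, 0.58 for Emcn and 0.54 for Cdh5, which encodes VE-cadherin of endothelial junctions. Nos3, the endothelial nitric oxide synthase, went the other way at -0.43 and lacked a promoter peak in db/db. Of all genes with a peak, 28.5% held more peaks in db/db and 12.4% fewer. The list lay at percentile 94.8, inside the central range, when loci were limited to 10 kb around the TSS.

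The contractile smooth muscle list was not apart in db/db over db/+. Of its 22 members, 6 held more peaks in db/db, 9 the same number and 7 fewer, and the median of -0.10 lay at percentile 7.20, but in 3 of 11 other settings it lay below the central range, at the lowest at percentile 0.38. Over all genes with a peak the median was -0.08. The lowest ratios were -0.82 for Des (desmin), -0.50 for Pln (phospholamban), -0.43 for Myl9 and -0.36 for Tpm2. The modulated smooth muscle list, which holds genes of synthetic and cartilage-like cells, was not apart either, with a median of -0.10 and 5 members higher in peak number, 11 equal and 4 lower. Its largest ratios were -0.67 for Timp1, -0.61 for Sox9 and 0.42 for Cytl1, while Ibsp held 0 peaks in db/+ and 1 in db/db. In 1 of 11 other settings this list lay below the central range, at percentile 1.70. The other 27 lists lay between percentiles 5.56 and 81.8. All differences between db/db and db/+ run together with batch 1 against batch 2, and the group and the batch cannot be told apart. Gavage may differ between these groups as well, since none is recorded here for db/+.

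At promoters, 257 genes had a peak in db/db and none in db/+, and 164 had the reverse, out of 21728 genes, of which 15432 and 15339 had a promoter peak. With lists of equal length the counts were 238 and 488. This setting shortens the db/db list and leaves the db/+ list whole, so the direction of both changes was fixed in advance. Among list members, the promoters of Csf1r and Spi1, a growth factor receptor and a transcription factor of macrophages, had a peak in both db/db libraries and none in db/+. The Spi1 peak of db/db lay on chromosome 2 from 91082648 to 91083540. The same held for Pi16, a marker of adventitial fibroblasts, with a db/db peak on chromosome 17 from 29316685 to 29317601, and for Lyve1, Zap70, Fgb and Tbr1. C1qa and C1qc, complement genes of macrophages, and Nlrp3, an inflammasome sensor, had a promoter peak in db/+ alone, as did Upk1b. Lep, which encodes leptin, Bcl11b and Ahsg had one in db/db alone.

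**Figure D1:**
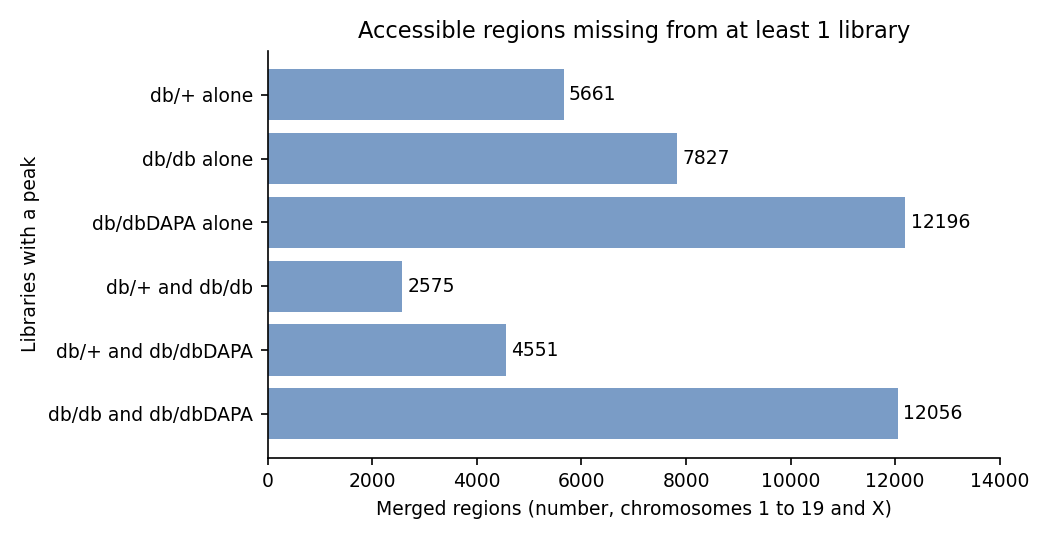
Number of merged regions on chromosomes 1 to 19 and X (horizontal axis) that hold a peak in each combination of libraries (vertical axis), leaving out the 100000 regions found in all 3 libraries. Among combinations of 2 libraries, the 12056 regions shared by db/db and db/dbDAPA exceeded the 4551 shared by db/+ and db/dbDAPA and the 2575 shared by db/+ and db/db.

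The comparison of db/dbDAPA with db/db, both of batch 1, addresses what treatment changes in the diabetic aorta. The oxidative stress list was apart, although a second list of 25 other antioxidant genes, at percentile 46.8, was not. Of the 20 members, 12 held more peaks in db/dbDAPA, 6 the same number and 2 fewer, with 91 peaks in db/dbDAPA against 73 in db/db and 70 in db/+. Among all genes with a peak, 24.5% held more peaks in db/dbDAPA than in db/db and 13.2% fewer. Txnrd1, thioredoxin reductase (chromosome 10, 82833951 to 82897712), held 4 peaks in db/dbDAPA and 2 in db/db, a log2 ratio of 0.77. Sod2, the mitochondrial superoxide dismutase (chromosome 17, 13006846 to 13040063), also held 4 and 2, with 0.63, and Srxn1, sulfiredoxin, held 2 and 1 with 0.60. Cybb, the catalytic subunit of the phagocyte NADPH oxidase, held 3 peaks in db/dbDAPA, 1 in db/db and 0 in db/+. The median of the list was 0.24 against -0.04 for all genes, and 0 of 10000 random lists reached it. With lists of equal length it lay at percentile 91.5, inside the central range.

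**Figure D2:**
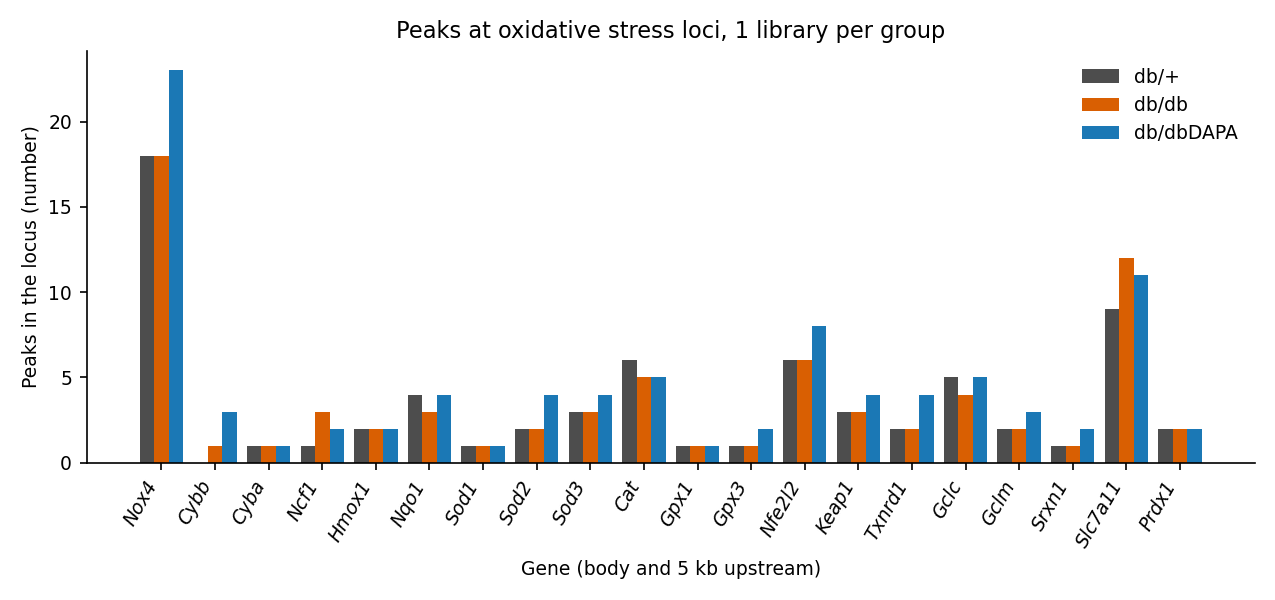
Number of peaks (vertical axis) in the locus of each of the 20 oxidative stress genes (horizontal axis), with 1 bar per library. Nox4 held 18 peaks in db/+ and in db/db and 23 in db/dbDAPA, whereas Slc7a11 held 9, 12 and 11 and Cat held 6, 5 and 5.

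Of the genes with the highest ratios in db/dbDAPA over db/db, Dmp1, a protein of mineralised matrix (chromosome 5, 104202613 to 104214102), held 4 and 1 peaks with a log2 ratio of 1.69, which became 1.01 with lists of equal length and 2.35 with a pseudocount of 100 bp. Mdm2, the ubiquitin ligase of p53 (chromosome 10, 117688875 to 117710758), held 5 and 2 with 1.48. Vil1, the microvillar protein villin (chromosome 1, 74409376 to 74435559), held 4 and 1 with 1.49. Sem1, second to Dmp1, and Kcnk12, Plekhs1, Capn6, Fam57a, Usp50 and Csrnp3, down to 1.11 for Csrnp3, completed the highest 10. All 4 db/dbDAPA peaks absent from db/db in Fam57a also lay in an overlapping gene. Cand1, which exchanges cullin ligase adaptors (chromosome 10, 119199255 to 119240055), had the lowest ratio, -1.51, with 1 peak in db/dbDAPA and 4 in db/db. It was followed by Mtx2, Ggnbp2, Cfap69, Mphosph9, Tvp23a, Acsl5, Papss1, Fam98b and Mycbp2, up to -0.98 for Mycbp2. In Acsl5 the 2 db/db peaks absent from db/dbDAPA also lay in another gene. Plekhs1 and Csrnp3 were also among the 10 lowest in db/db over db/+. Plekhs1 held 4, 1 and 4 peaks in db/+, db/db and db/dbDAPA, and Csrnp3 held 5, 2 and 5. The db/db library is common to both comparisons, so a peak missed in it counts as lower in the first and higher in the second.

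Genome-wide, 16847 of 129168 db/dbDAPA peaks (13.0%) had no overlapping peak in db/db, and 10469 of 122737 db/db peaks (8.53%) had none in db/dbDAPA. Promoter peaks were found in db/dbDAPA alone for 214 genes of this pair and in db/db alone for 166, counts that became 207 and 400 with lists of equal length. Nos3, the fibroblast genes Dpt and Clec3b, and Tnf, a cytokine, had a promoter peak in db/+ and db/dbDAPA and none in db/db. The Nos3 peak of db/dbDAPA lay on chromosome 5 from 24364305 to 24365186. Tcf21, a fibroblast transcription factor, Cx3cr1, a chemokine receptor of monocytes, and Krt19 had one in db/dbDAPA alone. Laptm5 and Gad2 had one in db/+ and db/db and none in db/dbDAPA. Tcf21 held 0 peaks in its locus in both other libraries and 2 in db/dbDAPA.

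Besides oxidative stress, 3 of the 30 lists were apart in db/dbDAPA over db/db. Lipid and PPAR genes had a median of 0.01 at percentile 99.2, with 11 of 24 members holding more peaks in db/dbDAPA, 11 the same number and 2 fewer. Lpl, lipoprotein lipase, had a log2 ratio of 0.68, Abca1, a cholesterol exporter, 0.51, Srebf2 0.36 and Nr1h3 -0.33. This list fell inside the central range at percentile 57.1 for loci of 10 kb around the TSS, at 96.9 by the number of peaks and at 94.3 without its most extreme member. Adipocyte genes had a median of -0.07 at percentile 0.27, although 10 of 14 members held the same number of peaks. Scaling gives unchanged loci a slightly negative ratio here, and the median over all genes with a peak was -0.05. The low percentile therefore need not reflect a loss of peaks. Hepatocyte genes, from a tissue not sampled, lay at percentile 0.79 with a median of -0.05, and 10 of 12 members held the same number of peaks, so that offsets of this size also occurred in a background list, which lay at percentile 19.4 by the number of peaks. The contractile smooth muscle list lay at percentile 87.3, with 13 members holding more peaks in db/dbDAPA, 6 the same number and 3 fewer. Nexn had a log2 ratio of 0.52, Des 0.40, Tpm1 0.38 and Tagln -0.39. The modulated smooth muscle list lay at percentile 88.8, with Ibsp at 0.69, Ly6a at 0.61 and Tnfrsf11b at -0.43. In 1 of 11 other settings the list lay above the central range, at percentile 99.8. The 26 lists that were not apart, these among them, lay between percentiles 3.47 and 92.0.

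**Figure D3:**
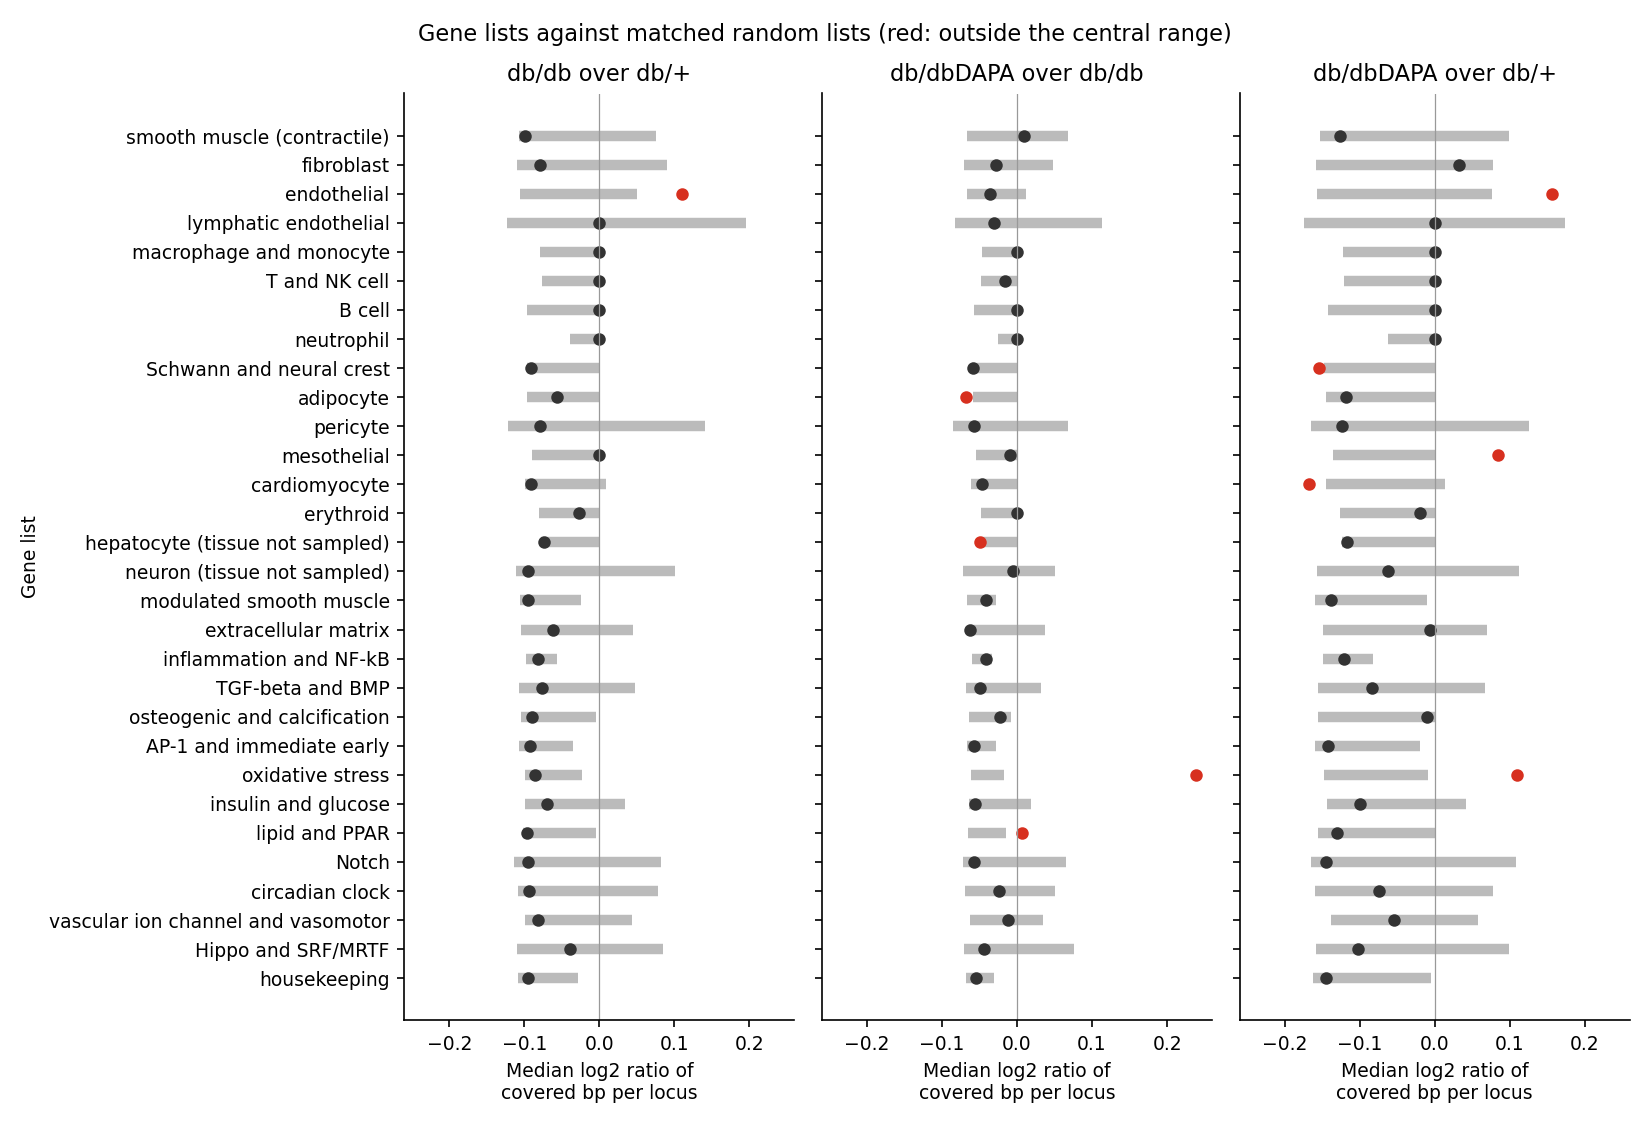
Median log2 ratio of covered bp per locus (horizontal axis) of each of the 30 gene lists (vertical axis) in the 3 comparisons of libraries. Points are list medians, grey bars hold the central 95% of 10000 matched random lists, and red points lie outside them, as oxidative stress does at 0.24 in db/dbDAPA over db/db.

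The comparison of db/dbDAPA with db/+ addresses how far the treated diabetic aorta stays from the control. Cadps, a factor of secretory vesicle release (chromosome 14, 12372563 to 12823079), held 3 peaks in db/db, 0 in db/+ and 4 in db/dbDAPA, all intronic in the last. Antxr2 held 8 peaks in db/dbDAPA and 1 in db/+, a log2 ratio of 2.41, Exoc5 held 8 and 1 with 2.07, and Chrm2 held 5 and 1 with 1.91. Tle4, a transcriptional corepressor (chromosome 19, 14448150 to 14598051), held 13 and 3 with 1.79, and Pi16 held 6 and 1 with 1.74. Caprin2 had the lowest ratio, -1.83, with 1 and 5 peaks, followed by Begain with -1.64, Gm20547 with -1.48 and Hrc with -1.39, which became -2.49 with lists of equal length.

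Abca8b, Hs3st5, Spata6 and Dmp1 (1.62, but 0.98 with lists of equal length) completed the highest 10, and Chd7, Cacng7, Bcl2l13, Aven, Dnah12 and Rsbn1 the lowest 10. Of the 10 highest genes in db/db over db/+, 4 were also among the 10 highest here (Antxr2, Chrm2, Exoc5 and Spata6), and 3 of the 10 lowest were also among the lowest (Caprin2, Gm20547 and Hrc). The db/+ library is common to both comparisons, so a peak missed in it counts in both. Genome-wide, 24338 db/dbDAPA peaks (18.8%) had no overlapping peak in db/+, and 8281 db/+ peaks (7.33%) had none in db/dbDAPA, a count that became 18622 with lists of equal length. Promoter peaks were found in db/dbDAPA alone for 277 genes of this pair and in db/+ alone for 136, against 239 and 682 with lists of equal length. Since that setting leaves the db/+ list whole, the direction of these changes was fixed in advance.

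The endothelial list was apart in this comparison, which shares the db/+ library with that of db/db over db/+, whereas it lay at percentile 82.7 in db/dbDAPA over db/db. Of 18 members, 12 held more peaks in db/dbDAPA, 6 the same number and 0 fewer, with a median of 0.16 at percentile 99.7. Among all genes with a peak, 33.6% held more peaks in db/dbDAPA than in db/+ and 9.10% fewer. Cytl1 had a log2 ratio of 0.69, Emcn 0.60, Robo4 0.55 and Cdh5 0.47. Oxidative stress genes had a median of 0.11 at percentile 99.8, with 12 of 20 members holding more peaks in db/dbDAPA. With lists of equal length these lists lay at percentiles 93.9 and 96.7, inside the central range, as did the endothelial list at 92.7 for loci of 10 kb around the TSS. Mesothelial genes lay at percentile 99.3 with a median of 0.08, where Msln held 1 peak in db/dbDAPA and 0 in both other libraries, but at percentile 0.81 with lists of equal length, 78.7 without the most extreme member and 94.2 for loci of 10 kb around the TSS. Cardiomyocyte genes had a median of -0.17 at percentile 0.19 and Schwann cell genes -0.15 at percentile 0.76. In these lists 7 of 10 and 8 of 12 members held the same number of peaks in both libraries. The cardiomyocyte list lay below the central range in 10 of 11 other settings, at percentile 0.06 by the number of peaks. For loci of 10 kb around the TSS it lay at percentile 75.0. Scaling gives unchanged loci a negative ratio here too, and the median over all genes with a peak was -0.12. The Schwann cell list was apart in 6 of 11 other settings and lay at percentile 31.6 by the number of peaks. The contractile and modulated smooth muscle lists lay at percentiles 14.3 and 36.1, and in 1 of 11 other settings the contractile list lay below the central range, at 1.43. The median over all genes was -0.10, and this comparison also sets batch 1 against batch 2.

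The title of the series asks about changes that persist under treatment. Of the 19947 db/db peaks absent from db/+, 12120 (60.8%) overlapped a db/dbDAPA peak. Of the 10258 db/+ peaks absent from db/db, 5661 (55.2%) were absent from db/dbDAPA as well, and 44.8% were present there. With the roles of the libraries exchanged, db/db held 49.9% of the db/dbDAPA peaks absent from db/+ and 31.6% of the db/+ peaks absent from db/dbDAPA. The db/+ library held 25.2% of the db/db peaks absent from db/dbDAPA and 27.6% of the db/dbDAPA peaks absent from db/db.

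Because db/+ enters both comparisons, a share above 0 arises with no effect. In 1000 simulations in which libraries differed only in how readily each called any region, db/dbDAPA held 55.5% of merged regions found in db/db and not db/+, against 60.6% observed; 95% of simulations lay between 54.9% and 56.0%. It lacked 44.5% (43.6% to 45.4%) of those in db/+ and not db/db, against 55.4% observed. For regions in db/db and db/dbDAPA alone the simulations gave 10574 (10439 to 10707), against 12056 observed. These simulations were added after the shares were seen, and the excess over them was not separated from batch. Their ranges hold only counting noise over regions treated as independent. They contain no spread between libraries or animals, so they cannot show whether the excess would recur. They were fitted to the same regions, so a real difference of a library that acts on all regions alike is absorbed in them. At promoters, 147 genes had a peak in both db/db libraries and none in db/+, 84 in db/+ and db/dbDAPA alone, and 56 in db/+ and db/db alone.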

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

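The settings that drop members from the gene lists were chosen after seeing the data. All 180 log2 ratios of the genes with the highest and lowest values under other settings kept their sign. That was all but fixed, since these genes were chosen for extreme ratios and the settings reuse the same peaks. Of the 180, 8, all of Hrc, Dmp1 or Cadps, moved by more than 1.5 times. Of 30 counts of peaks without overlap, 28 stayed within 1.5 times, as did 21 of 30 promoter counts and 23 of 33 counts of lists set apart. With lists of equal length, 16676 db/+ peaks had no overlap in db/db and 18622 none in db/dbDAPA. Trimming the 2 longer lists produces this by construction. The share of gained peaks held in db/dbDAPA was then 56.5% and the share of lost peaks still absent 76.5%. Promoter peaks were found in db/+ and not db/db for 488 genes, in db/+ and not db/dbDAPA for 682, and in db/db and not db/dbDAPA for 400. The same trimming fixed the direction of the rises in db/+. The number of lists apart was 8 for db/db over db/+ and 8 for db/dbDAPA over db/+, and the mesothelial list turned from above to below at percentile 0.81.

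With peaks at least as wide as the median, the gained and lost shares were 52.4% and 58.3%. Promoter counts were 942 (db/db, not db/+), 1088 (the reverse), 789 (db/dbDAPA, not db/db), 634 (the reverse), 971 (db/dbDAPA, not db/+) and 962 (the reverse), since fewer promoters keep a peak. With peaks within 250 bp counted as shared, the gained and lost shares were 61.5% and 53.9%. Lists apart in db/db over db/+ numbered 2 for loci of 10 kb around the TSS, 3 for the number of peaks, 2 for a pseudocount of 100 bp, 3 for the mean over members, 3 for scaling to the median gene, 2 for genes with a peak alone and 2 without members of several lists. In db/dbDAPA over db/db 2 lists were apart by the number of peaks. The cardiomyocyte list in db/dbDAPA over db/+ changed side at 10 kb around the TSS, at percentile 75.0, and stayed below the central range in 10 of 11 settings. Except where a construction is named, the cause was not tested. The adipocyte list in db/dbDAPA over db/db stayed apart in 11 of 11 settings, and the oxidative stress list in 10 of 11 there and in 10 of 11 over db/+. Of the 14 adipocyte genes, 10 held the same number of peaks in both libraries, and scaling tends to give such loci a slightly negative ratio.

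No paired analysis was possible because each group had 1 library, and no replicate was at hand to leave out. Depth is unknown, so a missing peak can reflect fewer fragments as well as less accessible chromatin. In each library the narrowest decile of peaks was shared least: 68.2% of that decile in db/db overlapped a db/+ peak, against 85.5% of the widest.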

Other observations

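Tests on the single extreme list member, on the Dmd locus and on the batches were chosen after the results were seen. Several long genes, chosen after their values were seen, collected many regions found in both db/db libraries and not in db/+. Gm20388 (57 of 648 regions) and Fgfr2 (31 of 296) had the most, over annotated spans that cross other genes. Lpp, a focal adhesion protein abundant in smooth muscle (chromosome 16, 24393507 to 24992578), held 28 such regions of 130 in its locus. Foxp1 held 20 of 117, Mast4 19 of 100 and Pcdh7 19 of 99, and 8.32% of all 144866 regions had this pattern. Of all regions, 8.42% were found in db/dbDAPA alone, as were 44 of 648 in Gm20388 and 27 of 296 in Fgfr2. Zbtb20 held 19 such regions among 122, and Kcnma1, the pore subunit of the large-conductance potassium channel of smooth muscle, held 15 among 101.

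Single vasomotor, fibroblast and calcification genes differed in peak number. None of these lists, nor the extracellular matrix list, was apart in any comparison at the settings fixed first. Agtr1a, an angiotensin II receptor, held 2, 1 and 3 peaks in db/+, db/db and db/dbDAPA. Col1a2, a chain of type I collagen in the fibroblast list, held 5, 4 and 10 peaks, with a log2 ratio of 1.07 in db/dbDAPA over db/db. Enpp1, which makes the calcification inhibitor pyrophosphate, held 7, 6 and 4 with -0.63. Pde3a, a cyclic nucleotide phosphodiesterase, held 40, 55 and 57 peaks, a ratio of 0.37 in db/db over db/+. The vasomotor list lay at percentiles 20.7, 83.5 and 56.7 in db/db over db/+, db/dbDAPA over db/db and db/dbDAPA over db/+. In the same order the extracellular matrix list lay at 62.6, 3.47 and 84.3, and the osteogenic and calcification list at 26.8, 92.0 and 96.6. The fibroblast list lay at 33.65, 73.7 and 91.9. It lay above the central range in 1 of 11 other settings for db/dbDAPA over db/db (99.95) and in 2 for db/dbDAPA over db/+ (at most 99.8). Among 11 other settings, the vasomotor list lay above the central range in 1 for db/db over db/+ (98.3) and 1 for db/dbDAPA over db/+ (99.8), and the osteogenic list in 1 for db/dbDAPA over db/db (99.4) and 2 for db/dbDAPA over db/+ (at most 98.0).

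Regions shared by db/db and db/dbDAPA alone outnumbered those shared by db/+ and db/dbDAPA alone 2.65 times and those shared by db/+ and db/db alone 4.68 times. With lists of equal length the ratios were 2.42 and 1.62. A fall of the first to 1.1 had been set in advance as the mark of longer lists, and it did not occur. The excess thus remained when the lists held equal numbers of peaks. That setting drops the narrowest peaks of the longer lists and does not undo unequal calling, so it cannot decide whether such calling made the excess. Regions in db/+ and db/db alone rose from 2575 to 5821 under it. With peaks at least as wide as the median the ratios were 1.77 and 2.17. In the simulations of unequal calling alike at all regions, db/db and db/dbDAPA alone shared 10574 regions, against 12056 observed. The pairs of db/+ with db/dbDAPA and with db/db alone shared 5208 and 3400, against 4551 and 2575 observed. Such calling gave the same order of counts and a smaller excess. Unequal calling that differs between regions was not tested and stays open. A batch effect and the db genotype also stay open, since 0 batches hold both a db/+ and a db/db library, and genotype and batch cannot be told apart.

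Oxidative stress loci held more peak coverage in db/dbDAPA than in db/db. Of its 20 members, 12 held more peaks in db/dbDAPA, so the median did not rest on a single member. Without the most extreme member the list stayed at percentile 100, but a median over 20 members all but fixes that outcome. A wider rise of antioxidant genes is not borne out: a second list of 25 other antioxidant and NADPH-supplying genes, written before its values were seen, lay at percentile 46.8, with 9 members holding more peaks in db/dbDAPA, 13 the same number and 3 fewer. The longer peak list of db/dbDAPA remains a candidate explanation, since with equal list lengths the percentile was 91.5. An effect of treatment on the 20 genes themselves is a hypothesis that also stays open, without replicates to test it.

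Dmd, which encodes dystrophin (chromosome X, 82948870 to 85206141), held 131 regions, of which 65 (49.6%) were found in 1 library alone: 30 in db/+, 20 in db/db and 15 in db/dbDAPA. Genome-wide the share was 17.7%. Other X-linked genes did not generally have such a share, as the median was 16.7% over 14 of them with at least 20 regions. Nor did other genes with many regions or of great length. The medians were 17.8% over 134 other genes with at least 50 regions and 20.8% over 28 other genes of at least 1 Mb with at least 20 regions, of which the highest had 31.1%. Dmd was chosen after its values were seen, so lower medians elsewhere were likely from the start. Each comparison takes 1 property alone and cannot exclude that they act together. Marginal peak calls are a candidate explanation: Dmd peaks found in 1 library had a median width -40 bp relative to those found in all 3 (831 against 871 bp), although peaks genome-wide showed a like difference (833 against 883 bp), and no biological explanation was tested.

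Chromosome Y held 0.0327% of peaks in db/+, 0.0374% in db/db and 0.0317% in db/dbDAPA, and unplaced scaffolds held 0.0601%, 0.0659% and 0.0596%. Between 44 and 63 barcode sequences were common to each pair of libraries.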
